A study of Mus musculus with 7 samples.

How the data were processed

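Luminal cells were sorted by flow cytometry from mouse prostates, per the labels, as negative for the lineage markers CD31, CD45 and Ter119, negative for Sca1 and positive for CD49f, and the T-ETV1 cells additionally as GFP positive. Total RNA was extracted with Trizol, amplified to cDNA with a NuGEN V2 kit and hybridised to Affymetrix 430 2.0 arrays, per the labels' protocols. The series text speaks of 3 biological replicates, while the labels name 3 WT and 4 T-ETV1 arrays, and all 7 were used.

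The deposited values are intensities on a linear scale, 1 per probe set and array, for 45037 probe sets. The method that made the deposited intensity of a probe set from its probes, and how the authors scaled the arrays, are not given in the sources used here. Of the deposited values 1907 (0.605%) were at or under 1. Control probe sets were not analysed here, so the ratio of 3' to 5' control signal was not used as a measure of RNA quality. The median of log2(intensity + 16) over all probe sets differed by at most 0.476 between arrays. This was under the limit of 0.5 set in advance, above which the values would have been quantile-normalized, and the deposited scaling was kept. The mean of the array medians of the log2 values was 6.28 ± 0.20 (SD, n = 3) in WT and 6.14 ± 0.12 (SD, n = 4) in T-ETV1 (exact two-sided permutation p = 0.400).

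Values were transformed as log2(intensity + 16), so that all differences are on that scale and understate the change of genes at low intensity. Probe sets were named through the platform annotation, in which 34945 had 1 gene symbol, 932 several and 9160 were not listed. Symbols were updated by Entrez ID for 34741 of them with a gene table of the assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Probe sets with several genes or none were left out. Of several probe sets of a gene the one with the highest mean over the 7 arrays stood for it, which left 18194 genes. Among the list members named, Hsd17b7, Lama3, Synpo2, Top2a, Sh2b3, Sesn2 and Cd4 also had a probe set of opposite sign.

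Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, T-ETV1 minus WT, two-sided, 6.67 total degrees of freedom) and Benjamini-Hochberg adjustment, with a threshold of 0.05. The 32 gene lists were written from general knowledge before the data were examined. They and the mouse Reactome pathways shipped with fgsea 1.28.0 that held 10 to 300 measured genes were tested with camera, which asks whether the genes of a set differ from the other genes, with a preset correlation between genes of 0.01. Lists needed 5 or more measured genes. Camera with an estimated correlation, camera on ranks and fry were run beside it. A list score is the mean over its genes of the deviation from the 7-array mean.

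Genes named in the text were chosen by a rule fixed before the data were examined. It names 7 genes chosen for the design, such as the promoter gene and those of the sort gate, of which 4 are reported and the others were not analysed here. It further names the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with groups that do not overlap. Where fewer than 20 pass, it adds those with the smallest unadjusted p up to 20 in all, given as not past the threshold. Of each list it names up to 4 members with the smallest p; for lists not called, those with an unadjusted p under 0.05 are given. Predicted genes and genes with only a clone name are not named. Genes chosen after their values were seen are said to be so.

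The replicate letters A to C occur in both groups, and whether they pair the arrays was checked before any fit with a block. Deviations from the group means correlated at 0.281 for the A arrays, 0.217 for the B arrays and 0.356 for the C arrays, all over the limit of 0.1 set for pairing, and each was the highest of its array. WT A and T-ETV1 D, of unlike letters, were also over the limit, at 0.187, so the limit alone does not part like from unlike letters. The pairing comes from the letters in the labels and this correlation. The fit without the block was the one planned as the main result, and the fit with the block used the arrays A to C.

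The alternatives were quantile normalization, median centring, a pseudocount of 1 or 64, leaving out the lowest 30% or 50% of genes, the mean of a gene's probe sets, every probe set on its own, eBayes with a trend or with robust settings, array weights, the replicate block, leaving out each array in turn, and for changed genes a threshold of 0.1 and an added minimum log2 difference of 1. Exact permutation tests went through the 35 splits of 7 arrays into 3 and 4. The tests were tried on simulated data, drawn for the 18194 genes from their means and residual SDs, for T-ETV1 against WT with 4 against 3 arrays. Each gene was drawn independently of the others. The structure that genes share in the real arrays was left out, so these rates are not the power of the real comparison. Of 50 genes changed by 1 on the log2 scale 52.0% were recovered, of 50 changed by 2 76.0%, of 50 changed by 3 86.0% and of 50 changed by 4 92.0%, with 10 unchanged genes called. Of 200 simulated changes by 1 among genes with a low residual SD, 98.5% were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.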

Results

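Gene expression was measured with Affymetrix 430 2.0 arrays in luminal cells, the secretory epithelial cells that line the prostate gland, sorted from mouse prostates. There were 3 arrays of wild-type cells (WT, replicates A to C) and 4 of T-ETV1 cells (replicates A to D). T-ETV1 mice carry a human ETV1 cDNA, an ETS transcription factor that is fused to TMPRSS2 in some prostate cancers, under the mouse Tmprss2 promoter. The comparison asks how the luminal cell transcriptome differs with this allele. T-ETV1 cells were also gated on GFP and WT cells were not, so genotype and gate cannot be told apart. The median intensity of an array lay between 48.5 (T-ETV1 A) and 73.7 (WT C), and Spearman correlations between arrays lay between 0.896 and 0.942. The first principal component held 45.3% of the variance, with WT C at 87.9 and T-ETV1 C at 41.6, while T-ETV1 A, B and D lay between -43.8 and -42.0. The number of arrays limits the precision of every value given here.

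No gene passed the threshold between T-ETV1 and WT: 0 of 18194 genes had a limma adjusted p under 0.05, and the smallest adjusted p was 0.485. The gene with the smallest unadjusted p was Polr3gl, which encodes a subunit of RNA polymerase III. Its log2 difference, T-ETV1 minus WT, was -2.17 ± 0.22 (SE), from a mean log2 value of 9.66 ± 0.08 (SD, n = 3) in WT and 7.49 ± 0.39 (SD, n = 4) in T-ETV1. The 20 genes with the smallest unadjusted p, of which 17 were lower and 3 higher, had adjusted p values between 0.485 and 0.581, and in each of them the groups of arrays did not overlap. The lower ones encode proteins of several kinds. Receptors among them were Kit, the stem cell factor receptor (-1.64 ± 0.27), Avpr1a, a vasopressin receptor (-2.30 ± 0.39), and Npy1r, a neuropeptide Y receptor (-0.89 ± 0.14). Aqp4, a water channel, had a difference of -1.30 ± 0.16 and Clic6, a chloride channel family member, one of -1.45 ± 0.25. Tph1, the first enzyme of serotonin synthesis, had -1.50 ± 0.20, and Evc, a protein of the primary cilium, had -1.53 ± 0.23. The GTPase regulators Arap3 and Arhgap10 had -1.07 ± 0.13 and -1.48 ± 0.23, and the small GTPase Rasl11a had -1.18 ± 0.19. The remaining lower genes were Vwa2 (-1.78 ± 0.24), the RNA gene Dio3os (-1.73 ± 0.29), Ocel1 (-1.19 ± 0.18), Zfp868 (-0.79 ± 0.12), Ciapin1 (-0.76 ± 0.12) and Mex3d (-0.75 ± 0.10). The 3 higher genes were Hapln4, a hyaluronan link protein (0.99 ± 0.17), Tmem200a (0.90 ± 0.15) and the RNA-binding protein Igf2bp1 (0.81 ± 0.12). Of the 20 genes, 13 had a mean intensity under 100 in both groups, and 3 (Igf2bp1, Ciapin1 and Npy1r) had another probe set of opposite sign. Polr3gl and Avpr1a passed the threshold without T-ETV1 C (adjusted p = 0.0317 for each).

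Tmprss2, whose promoter drives the transgene, had a log2 difference of -0.15 ± 0.19 (adjusted p = 0.944). Of the surface proteins used for sorting, Itga6 (CD49f), which was selected for, differed by 0.09 ± 0.21. Pecam1 (CD31) and Ptprc (CD45), which were selected against, differed by -1.23 ± 0.71 and -0.996 ± 1.17, with adjusted p values of 0.867 and 0.936. The sign of Itga6 turned without T-ETV1 C (-0.09) and with the mean of its probe sets (-0.04), and that of Ptprc turned without WT C (0.51). The luminal keratins Krt8 and Krt18 differed by 0.05 ± 0.18 and 0.02 ± 0.09, and the secretory protein gene Pbsn by -0.01 ± 0.08, close to the highest intensities of the arrays. These 3 were chosen after their values were seen.

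At an unadjusted p under 0.05 there were 1113 genes, against 910 expected by chance. Of these 364 were higher and 749 lower in T-ETV1, but the split depended on scaling: it was 608 higher and 582 lower after quantile normalization, and 703 higher and 492 lower after median centring, which moved the median difference of all genes from -0.03 to 0.11. In 1150 genes (6.32%) the groups did not overlap, against a share of 5.71% by chance. Without WT C, 7 genes passed the threshold (5 higher, 2 lower), among them H2-Q10, a class I histocompatibility gene chosen after its value was seen, at a log2 difference of 6.89. All 7 were genes at which WT A and WT B differed from the other 5 arrays by at least 1. Without T-ETV1 C, 27 passed (1 higher, 26 lower), among them Cldn5, a tight junction gene of endothelium, at -3.29 and Apoe at -4.84. Without both arrays C, an alternative chosen after seeing the data, 68 passed (10 higher, 58 lower).

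Several groups of marker genes of cell types other than luminal cells were lower in T-ETV1. Of 32 gene lists fixed before the data were examined, 6 were lower and 2 higher at a camera adjusted p under 0.05 (1 higher and 10 lower after either other scaling). All 18 endothelial genes were lower, with a mean log2 difference of -1.55 (adjusted p = 7.00e-08; 0.799 with an estimated correlation between genes; mean -0.95 without WT C). Examples were Plvap, a protein of endothelial diaphragms (-2.60 ± 0.51), Ptprb (-2.73 ± 0.72), Cldn5 (-2.56 ± 0.76) and the receptor Tie1 (-1.93 ± 0.65), of which Cldn5 passed over all genes without T-ETV1 C (adjusted p = 0.00181). Of 20 fibroblast and matrix genes 19 were lower, with a mean of -1.49 (adjusted p = 3.47e-06; 0.889 with an estimated correlation). The mean was -0.61 without WT C and -0.89 without both arrays C. Members included the collagens Col3a1 (-2.91 ± 0.84), Col1a2 (-2.36 ± 0.82) and Col5a2 (-1.81 ± 0.60) and the lipocalin Apod (-2.86 ± 0.68). Of 15 smooth muscle genes 14 were lower, with a mean of -1.41 (adjusted p = 5.16e-06; 0.799 with an estimated correlation; mean -0.86 without WT C). Myl9, a myosin light chain, had -3.60 ± 0.87, the pericyte receptor Pdgfrb -2.47 ± 0.45, Mustn1 -1.72 ± 0.55 and Synpo2 -1.19 ± 0.35. All 19 genes of the epithelial to mesenchymal transition list were lower (mean -1.40, adjusted p = 9.25e-06; 0.799 with an estimated correlation). The mean was -0.84 without WT C. A covariate, chosen after seeing the data, was the mean score of 6 other-cell lists (basal, leukocyte, myeloid, endothelial, fibroblast and smooth muscle). This covariate was -0.43, 0.15 and 2.35 in WT A, B and C. It was -0.94, -0.91, 0.62 and -0.83 in T-ETV1 A, B, C and D. It thus itself differed between the genotypes, so a fit with it can also take out a genotype difference. A smaller mean or a lost call cannot tell cell share from genotype. With the covariate the mean of the epithelial to mesenchymal list was -0.37 and the call ended (adjusted p = 0.0970). Among the genes of that list were the smooth muscle actin Acta2, also in the smooth muscle list (-2.90 ± 0.99), Vim, an intermediate filament of mesenchymal cells (-2.70 ± 1.01), Zeb2 (-1.58 ± 0.58) and Cdh2 (-1.19 ± 0.27). All 12 neuroendocrine and neural genes were lower (mean -0.71, adjusted p = 0.00166, and 0.799 with an estimated correlation). With the covariate the mean was -0.43 and the list stayed called at the preset correlation (adjusted p = 0.0398). Members were Scg5 at -1.52 ± 0.44, Eno2 at -1.67 ± 0.73, the synaptic vesicle gene Syp at -0.81 ± 0.27 and Insm1 at -0.38 ± 0.12.

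Of 19 prostate basal cell genes 15 were lower, with a mean of -1.36 (adjusted p = 0.00537; 0.9996 with an estimated correlation), among them the apolipoprotein gene Apoe (-3.72 ± 1.19), the basal keratin Krt14 (-3.15 ± 1.47), Lama3, a laminin chain (-1.60 ± 0.65), and Bcam (-1.45 ± 0.49). The basal call ended without WT C (mean -0.96, adjusted p = 0.259) and without T-ETV1 A (mean -1.09, adjusted p = 0.0660), while without T-ETV1 C its members Apoe and Lama3 passed over all genes (adjusted p = 0.0216 and 0.0317). Without both arrays C the list was called at the preset correlation (mean -1.52, camera adjusted p = 0.000167). No member of these 6 lists passed over all genes; adjusted over the list alone, 1 endothelial gene (Plvap) and 2 smooth muscle genes (Pdgfrb and Myl9) did, and none of the other 4 lists. The levels varied widely between arrays of a group. Krt14 had log2 values of 7.88, 9.78 and 11.6 in WT A, B and C, and of 5.68, 5.17, 10.2 and 5.31 in T-ETV1 A, B, C and D. With an estimated correlation between genes none of the 8 calls held (the smallest adjusted p was 0.799), and fry, which asks only whether a list moves on balance, called none (smallest adjusted p = 0.707). By exact two-sided permutation of the list scores, for which 0.0571 is the smallest p that 3 against 4 arrays allow, p was 0.114 for the endothelial, fibroblast, smooth muscle and neural lists and 0.171 for the other 2. These p values leave the replicate letters aside. Within each of the 3 letter pairs T-ETV1 had the lower score in all 6 lists. T-ETV1 D has no pair, and 3 pairs alike in sign are too few to exclude chance. In all 6 lists the C arrays were the highest of their group, so the lists do not count as 6 separate observations. The endothelial score went from 0.01 to -0.82 for A, from 0.57 to -1.02 for B and from 2.07 to 0.33 for C, so that both C arrays were the highest of their group.

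**Figure D1:**
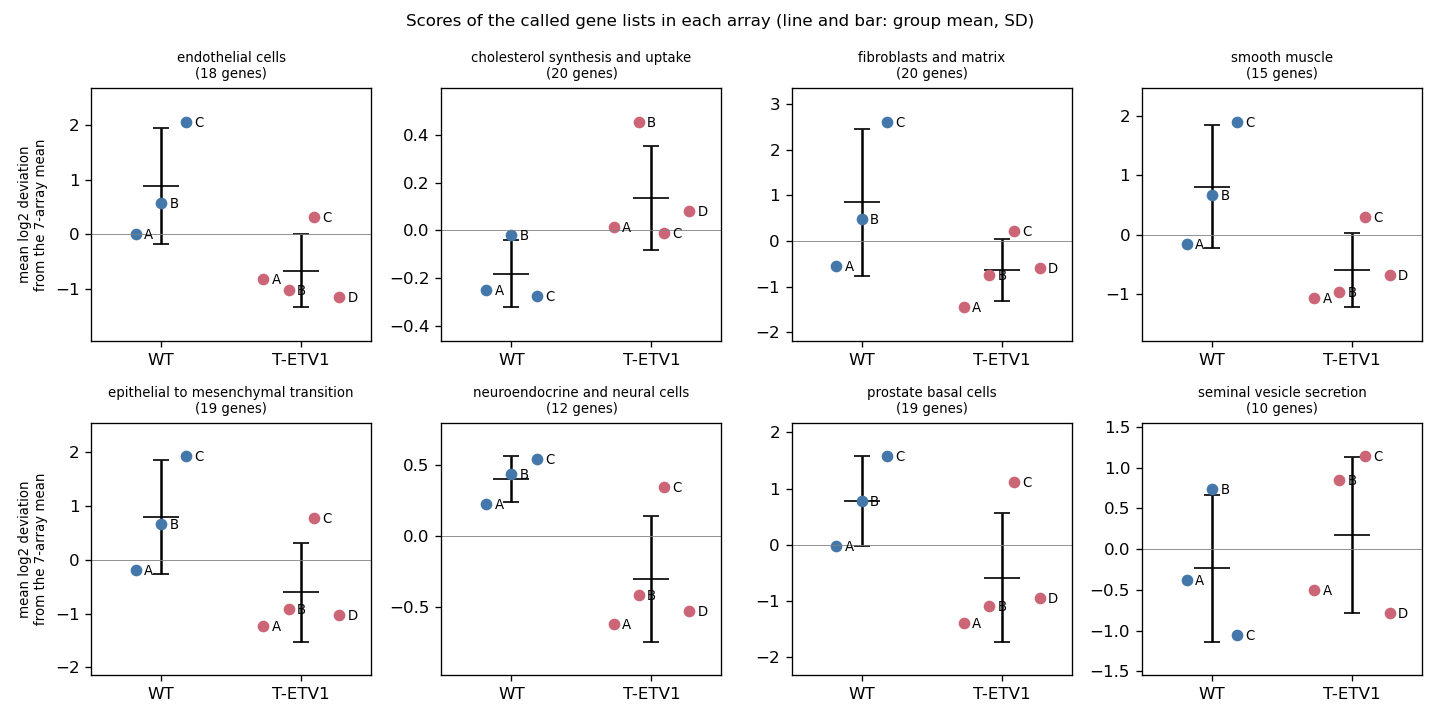
Score of each of the 8 called gene lists (the mean log2 deviation of its genes from the 7-array mean, vertical axis) in the WT and T-ETV1 arrays, with points lettered by replicate and a line and bar for the group mean and SD. WT C is the highest WT array and T-ETV1 C the highest T-ETV1 array for the 6 lower lists, while in the cholesterol list the 4 T-ETV1 arrays lie above the 3 WT arrays.

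Genes of cholesterol synthesis and uptake were higher in T-ETV1. Of 20 measured members 19 were higher, with a mean log2 difference of 0.32 (camera adjusted p = 3.31e-07; adjusted p = 0.799 with an estimated correlation). Sqle, the squalene epoxidase, had the smallest p, at 0.70 ± 0.20, followed by Msmo1 (0.50 ± 0.19), Fdft1, the squalene synthase (0.62 ± 0.24), and Hsd17b7 (0.67 ± 0.26), which had another probe set of opposite sign. None passed over all genes or adjusted over the list alone. The list score was higher in all 4 T-ETV1 arrays than in all 3 WT arrays (exact permutation p = 0.0571, the smallest possible here). Adjusted over all gene lists tested, that permutation p was 0.731, so the separation of the groups did not pass. The separation was narrow, since T-ETV1 C (-0.01) lay only just above WT B (-0.02). The list was called without each array in turn (mean 0.21, without T-ETV1 B, to 0.40, highest adjusted p 0.00132 without WT C).

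**Figure D2:**
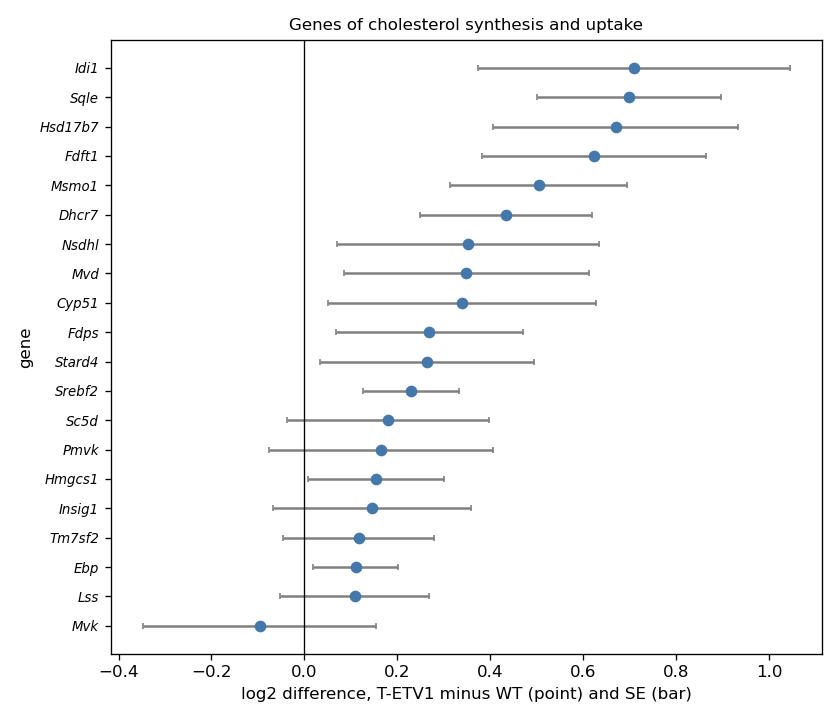
Log2 difference, T-ETV1 minus WT (horizontal axis), of the 20 measured genes of cholesterol synthesis and uptake (vertical axis), with bars for the SE of the limma fit over 3 WT and 4 T-ETV1 arrays. 19 points lie above 0.

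Fatty acid synthesis genes did not pass as a list (20 genes, mean -0.11, median 0.04, adjusted p = 0.357). Fasn, the fatty acid synthase, had 0.37 ± 0.10, Me1, the NADP-dependent malic enzyme, 0.73 ± 0.25 and the elongase Elovl7 -0.51 ± 0.11, none of which passed. The list of fatty acid oxidation (mean -0.07) had an adjusted p of 0.9995, oxidative phosphorylation (-0.02) 0.974 and glycolysis (-0.19) also 0.974. Ndufs1, a subunit of respiratory complex I, had -0.26 ± 0.10 and the phosphofructokinase Pfkp -1.47 ± 0.58.

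Seminal vesicle secretion genes were higher as a list, with 9 of 10 members higher and a mean of 0.41 (adjusted p = 0.0217; adjusted p = 0.799 with an estimated correlation), but the arrays of the groups overlapped (exact permutation p = 0.457). The secretory protein genes Svs6, Svs4 and Svs5 had 1.42 ± 0.89, 0.47 ± 0.23 and 0.18 ± 0.09, and Serpina1f had -1.42 ± 1.24. Svs4 and Svs5 lay close to the highest intensities of the arrays, where differences can be understated. None passed over all genes or adjusted over the list alone. The call ended without WT A (mean 0.34, adjusted p = 0.0652), without WT C (0.00, 0.176), without T-ETV1 B (0.19, 0.0988) and without T-ETV1 C (0.09, 0.139). It was kept without WT B (mean 0.90), without T-ETV1 A (0.64) and without T-ETV1 D (0.73). It also ended after quantile normalization (0.0735) and median centring (0.0966) and with the other-cell covariate (0.144), and with array weights the mean turned to -0.44.

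Programmes of luminal cells did not pass. The androgen response list had 80 measured genes, 37 higher and 43 lower (mean -0.17, median -0.01, adjusted p = 0.974), with Rab4a at 0.53 ± 0.15, Herc3 at 0.64 ± 0.26, Cdc14b at -1.39 ± 0.43 and Ndrg1 at -2.82 ± 1.15. Steroid hormone synthesis and metabolism (31 genes, mean -0.09) also had an adjusted p of 0.974, with the estrogen sulfotransferase Sult1e1 at -2.71 ± 0.93. Prostate luminal identity genes had a mean of -0.13 (adjusted p = 0.974), prostate secretory proteins 0.04 (0.597), proximal and progenitor-like luminal genes 0.05 (0.728), epithelial junctions and keratins 0.02 (0.904) and polyamine synthesis and turnover -0.06 (0.9995).

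Lists tied to signalling and growth were not called either. The list of ERK and FGF feedback genes had 15 of 20 members lower (mean -0.47, adjusted p = 0.0810; 0.9996 with an estimated correlation), with Etv4, an ETS factor, at -2.36 ± 0.72 and the adaptor Sh2b3 at -0.57 ± 0.22. With the replicate letter as a block, and the preset correlation as in every pass given here, this list passed (mean -0.40, adjusted p = 0.0388), as it did without WT A (mean -0.77, adjusted p = 0.00210), without T-ETV1 B (0.0341), without T-ETV1 C (0.0210), with array weights (0.0217) and after quantile normalization (0.0166) and median centring (0.00162). With the other-cell covariate its mean was 0.04 (adjusted p = 0.786). Proteases and invasion genes had a mean of -0.44 (adjusted p = 0.0875), with Adam17 at -0.48 ± 0.19, and passed without WT A (mean -0.77, adjusted p = 0.00223), without T-ETV1 C (0.0210), after quantile normalization (0.0478) and median centring (0.00372), and with each probe set on its own (0.00392). With the covariate its mean was 0.10. Without WT C the means were -0.16 for the ERK and FGF list and -0.10 for the proteases, neither passing. Cell cycle and proliferation genes had 17 of 35 members higher and a mean of -0.01 (adjusted p = 0.445), with the cyclin Ccne2 at 0.95 ± 0.22 and the topoisomerase Top2a at 0.39 ± 0.13; the list passed, with a mean of 0.10, without T-ETV1 D (adjusted p = 0.0388). The unfolded protein response (mean -0.06, adjusted p = 0.906) included Pdia4 at -0.74 ± 0.28, and passed with the other-cell covariate (mean -0.12, adjusted p = 0.0237). The p53 target list (mean -0.07, adjusted p = 0.974) held 1 gene past the threshold adjusted over the list alone, the stress protein gene Sesn2 at -0.84 ± 0.15. Glutathione and oxidative stress genes (mean 0.00, adjusted p = 0.951) and cytosolic ribosomal proteins (mean -0.02, adjusted p = 0.974) were not called.

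Immune lists moved with array WT C. Leukocyte genes had a mean of -0.68 (adjusted p = 0.242), and macrophage and myeloid genes one of -0.76 (0.136). Without WT C the means were 0.46 (adjusted p = 0.0321, now past the threshold and higher in T-ETV1) and 0.66 (0.266). Both lists passed as lower without WT A (means -1.27 and -1.52, adjusted p = 0.0150 and 0.00357), without WT B (-1.23 and -1.42, 0.00544 and 0.00580) and after median centring (0.00326 and 0.00142). The leukocyte list also passed with each probe set on its own (0.0488), and the myeloid list without T-ETV1 C (mean -1.37, adjusted p = 0.0207) and after quantile normalization (0.0298). The interferon response had a mean of -0.10 (adjusted p = 0.974), which became 0.30 and passed without WT C (adjusted p = 0.00791). Genes of NF-kB and inflammatory cytokines had a mean of -0.38 (adjusted p = 0.433), with the adhesion molecule Icam1 at -2.25 ± 0.75, and passed without WT A (mean -0.87, adjusted p = 0.0136) and, as higher, with the covariate (mean 0.48, adjusted p = 0.0418). Immediate early and dissociation stress genes had a mean of -0.25 (adjusted p = 0.260) and passed without WT A (mean -0.49, adjusted p = 0.00357), without T-ETV1 B (-0.40, 0.00279) and after quantile normalization (0.0428). Without WT C the means of these 2 lists turned to 0.27 and 0.03, neither passing (adjusted p = 0.497 and 0.849). Erythroid genes had a mean of -0.03 (adjusted p = 0.951). In 10 of the 24 lists not called the mean, median and test differed in sign, and none of the 24 had an adjusted p under 0.05 with an estimated correlation. Beyond Sesn2, none held a member past the threshold adjusted over the list alone.

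In an open search of 883 Reactome pathways, 15 were lower and 2 higher in T-ETV1, and none passed with an estimated correlation (smallest adjusted p = 0.996). The lower ones were led by matrix proteins: ECM proteoglycans (54 of 62 genes lower, mean -0.93, camera adjusted p = 8.71e-06), laminin interactions (27 of 29 lower, mean -1.09, adjusted p = 1.02e-05) and collagen formation (54 of 64 lower, mean -0.83, adjusted p = 0.000165). The others included integrin cell surface interactions (65 of 77 lower, mean -0.82) and axon guidance (181 of 248 lower, mean -0.35). The 2 higher pathways were cholesterol biosynthesis (17 of 21 genes higher, mean 0.27, adjusted p = 0.000220) and activation of gene expression by SREBF, the transcription factors of sterol genes (17 of 23 higher, mean 0.13, adjusted p = 0.0272). After quantile normalization 22 were lower and 1 higher, after median centring 34 lower and 1 higher, and with array weights 13 lower and 0 higher. With the replicate letter as a block 26 passed (24 lower, 2 higher). The count was 30 without WT A, 4 without WT C and 28 without T-ETV1 C, with 1 higher in each of these.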

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

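The 4 T-ETV1 values of each gene and list named were examined for an array far from the others. The measure was the gap to its nearest neighbour over the range, against Dixon's critical value for 4 arrays. Of 106 values 20 passed, against 5.30 expected by chance, since about 1 in 20 such groups is picked out without cause. The 106 come from the same 4 arrays, and list scores include genes tested singly. They are not independent, so the excess cannot be read as many separate results. The tests of WT C alone, of the gate, of a single T-ETV1 array, of other-cell share, of scaling and of a swap, and the splits for changed genes, were chosen only after the result was seen.

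T-ETV1 C was the array far from the others in 16 of the 20. On the log2 scale it was high for the endothelial genes Pecam1 (5.96, the others at most 4.64), Cldn5 (7.90, at most 4.99), Ptprb (6.43, at most 5.39) and Tie1 (6.32, at most 4.68). It was high for Krt14 (10.2, at most 5.68), Lama3 (10.5, at most 8.19) and Apoe (10.5, at most 6.29) of the basal list, for the smooth muscle actin Acta2 (8.52, at most 6.12) and for the leukocyte gene Ptprc (6.17, at most 4.60). Itga6 (12.1, at most 11.4), Pfkp (7.58, at most 6.38) and Dio3os (4.87, at most 4.37) were also high there. So were the mean log2 values of the lists of the epithelial to mesenchymal transition (8.28, at most 6.59), NF-kB and inflammatory cytokines (8.30, at most 7.55), steroid hormone synthesis and metabolism (7.49, at most 7.22) and p53 targets (9.20, at most 8.92). T-ETV1 B was high for Msmo1 (10.9, at most 10.4), Svs5 (13.7, at most 13.6) and epithelial junctions and keratins (11.8, at most 11.5). T-ETV1 D was low for Herc3 (9.60, the others at least 9.87).

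The first pattern is that the marker lists of other cell types were lower in T-ETV1. High levels in WT C alone stay open. Without WT C 5 of the 6 lower lists (all but basal) stayed past the threshold at the preset correlation, but with an estimated one none passed even with all arrays (adjusted p 0.799 to 0.9996). The group differences of the list scores without WT C were 1.01 to 1.88 SE over arrays, none beyond 2 SE. The means went from -1.49 to -0.61 for fibroblasts, -1.55 to -0.95 for endothelium, -1.41 to -0.86 for smooth muscle and -1.40 to -0.84 for the epithelial to mesenchymal list. Without both arrays C, chosen after seeing the data, these 4 means were -0.89, -1.29, -1.17 and -1.30, with -0.86 for the neural and -1.52 for the basal list. All 6 were then past the threshold at the preset correlation. This goes against WT C alone, but that fit also leaves out T-ETV1 C, the highest T-ETV1 array. A lower share of luminal cells in the WT sorts, raising every other cell type alike, stays open: the group difference of leukocyte markers lay above that of endothelial ones by 0.87 ± 0.51 (SE), or 1.71 SE, short of the 2 SE set in advance, and the sort removed CD31 and CD45 positive cells. The GFP gate may be the cause, but 0 of 3 WT arrays and 4 of 4 T-ETV1 arrays had it, so gate and genotype cannot be told apart. T-ETV1 C may carry a wrong label, which stays open. On 239 genes lower in T-ETV1 chosen without it, its median position between the WT mean (0) and the T-ETV1 mean (1) was -0.03. A, B and D, held out alike, lay at 0.96, 0.85 and 0.94, but on other sets of 17, 22 and 19 genes. Those sets were chosen with T-ETV1 C on the side of T-ETV1, so they leave out genes on which it departs. Other cell types, or what the paired C arrays share (correlation 0.356), would also place T-ETV1 C near WT. On the 6 genes higher in T-ETV1 chosen without it, T-ETV1 C lay at 0.34. A, B and D lay at 0.10, 0.10 and 0.52 on their own sets of 6, 3 and 2 genes.

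The second pattern is the higher cholesterol list. High levels in T-ETV1 B alone, the highest of the 4, are argued against only weakly. Without it the score still differed by 0.21 ± 0.09 (SE over arrays), or 2.42 SE, against 2.17 SE with all arrays. The difference was 1.94 SE without T-ETV1 D, 1.55 SE without WT A and 1.51 SE without WT C. The camera adjusted p with any array left out was at most 0.00132, but it rests on the preset correlation and does not hold this spread over arrays. Scaling is argued against, since the list mean minus the median of all genes was 0.34 as deposited and 0.35 after quantile normalization, with the call kept after quantile normalization and after median centring. The share of other cell types stays open: with the mean score of 6 other-cell lists as a covariate the list had an adjusted p of 0.0218 at the preset correlation, but a mean of 0.24 ± 0.18 (SE over arrays). The gate and the genotype stay open, and so does the correlation between its genes, with which the call was lost.

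The third pattern is a set of genes at which WT A and WT B differed from WT C and from all T-ETV1 arrays. H2-Q10 had log2 values of 4.91 and 5.17 in WT A and B and of 11.4 to 12.6 in the other 5 arrays, and Dnase1l2, Ugt8a and Slc6a2, chosen like H2-Q10 after their values were seen, had gaps of 3.85, 2.88 and 2.56. By definition WT C and T-ETV1 C lie together in this pattern, so exchanging their labels leaves it as it is. This argues against a swap of both arrays as its cause. Genes chosen without either array ask more widely whether the labels are swapped, which needs T-ETV1 C nearer WT where WT C lies nearer T-ETV1. Of 299 genes chosen without either, WT C lay nearer T-ETV1 in 49. In 14 of these T-ETV1 C lay nearer WT, and in 35 both lay nearer T-ETV1. The median position of WT C on the 299 was -0.38, on the side of its own label, though T-ETV1 C lay at -0.09, on the side of WT. The 2 directions differed. On the 264 genes lower in T-ETV1, WT C lay at -0.46 and T-ETV1 C at -0.16. On the 35 genes higher in T-ETV1 both lay on the side of T-ETV1, WT C at 0.84 and T-ETV1 C at 0.64. A strain variant shared by WT A and WT B stays open. Among 103 placed genes with a gap of at least 0.5, 21 had another within 5 genes along the chromosome. Matched random sets had 5.83, a ratio of 3.60 (permutation p = 0.0005, the smallest that 2000 sets allow). Of the 20 other pairs of arrays 1 (WT C and T-ETV1 D, 11 of 55 against 1.63) had as high a ratio. WT C and T-ETV1 B came close, with 13 of 83 against 3.79, a ratio of 3.43 (permutation p = 0.0015). WT B and T-ETV1 B had 7 of 66 against 2.34 (permutation p = 0.03). Such neighbours were thus not particular to WT A and WT B. The gap was not set in advance, and at a gap of at least 1 only 2 of 27 genes had a neighbour (permutation p = 0.19) and 4 of the 20 other pairs had as high a ratio.

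Chance in the grouping of arrays could not be excluded for the counts of gene lists and Reactome pathways, and for changed genes the comparison says nothing: all 35 splits of the 7 arrays into 3 and 4 must give at least the 0 of the real split. The highest other count of genes was 88, for T-ETV1 A, B and D against the rest, which points to a structure of the samples in which T-ETV1 C lies with WT. For gene lists 17 of the 35 splits gave 8 or more (highest other 14), and for Reactome pathways 9 gave 17 or more (highest other 68). Among the 8 splits that part all 3 letter pairs, the real one included, 3 gave as many lists (highest other 10). As many pathways came from 2 of them (highest other 30), and the highest other count of genes was 1. The split with 30 pathways, which also gave 8 lists, was T-ETV1 A, B and C against the rest. It differs from the real split only in the side of T-ETV1 D. It therefore carries much of the genotype difference and says little about chance.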

How the results depend on the processing

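The alternatives without the pair of C arrays and with an other-cell score as a covariate were chosen after seeing the data, all others before. No gene passed in any planned setting except without 1 array, where the count ran from 0 to 27; without both arrays C it was 68. Lists called ran from 7 to 13 without 1 array, against 8, were 5 with the lowest 50% of genes left out, where the endothelial, smooth muscle and neural lists had under 5 genes left, and 0 with an estimated correlation and 0 with fry. Pathways called, against 17, ran from 4 to 30 without 1 array, and were 35 after median centring, 9 with the lowest 50% left out, 42 with every probe set on its own and 0 with an estimated correlation. With the replicate letter as a block 26 pathways passed, and it changed no other call but that of ERK and FGF feedback. Except for the fits with fewer samples or genes the cause was not tested. The cholesterol list was called in all 19 planned settings with the preset correlation (mean 0.20 to 0.45, adjusted p 8.02e-09 to 0.00132), and the endothelial (highest adjusted p 0.000765), fibroblast (0.00852), smooth muscle (0.00132), epithelial to mesenchymal (0.00962) and neural (0.00889) lists wherever tested so; the basal list kept 17 and the seminal vesicle list 12 of 19. Directions turned, past the threshold before or after, for seminal vesicle genes (-0.44 with array weights, -0.32 without both arrays C), interferon response (0.44 without both arrays C), NF-kB and inflammatory cytokines (0.48 with the covariate), and without 1 array for cell cycle (-0.11 to 0.10), interferon response (-0.38 to 0.30) and leukocytes (-1.27 to 0.46). Of 500 values of the 24 uncalled lists in planned settings, 28 passed (25 with the same sign) and 59 changed sign without passing. Of the 74 genes named by the rule, 72 kept their sign in every planned setting and 5 passed in some. The robust setting was not run for lists, which camera does not offer. Of the 20 genes with the smallest p, 13 had mean intensities under 100, where this scale understates differences.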

Other observations

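The following 9 genes were chosen after their values were seen, because they part T-ETV1 A, B and D from the other 4 arrays, and no list was tested. Lyve1, Prox1, Flt4, Mmrn1 and Reln had log2 values between 8.05 and 10.8 in the 3 WT arrays and between 9.24 and 11.3 in T-ETV1 C, but between 4.14 and 6.45 in T-ETV1 A, B and D. Prox1, a transcription factor known from lymphatic endothelium, had 9.18, 9.26 and 8.99 in WT A, B and C, and 4.60, 5.88, 9.58 and 4.45 in T-ETV1 A, B, C and D. Sox10, known from glia, Gpm6b, Scn7a and Abca8a had values between 6.92 and 11.2 in WT, between 7.80 and 10.7 in T-ETV1 C and between 4.24 and 7.96 in T-ETV1 A, B and D. Over all arrays none of the 9 genes passed (Reln: -3.59 ± 1.49, limma adjusted p = 0.812).

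The next 5 genes were chosen after their values were seen, because they were high in WT C alone, and no list was tested. The mast cell proteases Cma1 and Mcpt4 had log2 values of 11.3 and 10.8 in WT C and at most 4.74 and 4.64 elsewhere. The mast cell carboxypeptidase Cpa3 had 9.67 in WT C and at most 5.02 elsewhere, and the B and T lymphocyte receptor genes Cd79a and Cd3g had 7.08 and 7.17 in WT C and at most 4.61 and 4.49 elsewhere. The T lymphocyte gene Cd4, also chosen after its values were seen, did not share this, with 6.14 in WT C but 6.43 in T-ETV1 A and 6.55 in T-ETV1 C (another of its probe sets had a difference of opposite sign). The basal keratin Krt5, chosen likewise, had 8.51, 10.6 and 11.2 in WT A, B and C, and 5.35, 5.02, 10.8 and 7.79 in T-ETV1 A, B, C and D.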
